A study of Nicotiana attenuata with 8 samples.

How the data were processed

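RNA was measured in leaves of 8 samples of Nicotiana attenuata, a wild tobacco, on one-colour Agilent arrays with Cy3-labelled cRNA. Per the labels, 4 samples carried the empty vector (EV) and 4 were silenced for CYP, and all were treated with 150 µg methyl jasmonate (MeJA) per leaf and harvested at day 3. Per the labels' protocols, RNA came from 30 mg of leaf and 0.5 µg of it was labelled. Samples were placed in groups, and given replicate numbers, from their titles.

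The authors deposited 1 scanner file per array, written by Agilent Feature Extraction. Its version is 10.7.3.1 per the file headers, whereas the submitters' processing notes give 9.5. Per the file headers, each spot has a processed signal, a median signal and a local background, all intensities on a linear scale, and flags for spots well above background, saturated or deviating. The processed intensity was already background-subtracted and detrended within the array, but the deposited values were not normalised between arrays. The authors also deposited a value table on the log2 scale. Its columns differed from log2 of the same array's median signal by less than 0.0001 on average, and at least 99.97% of probes lay within 0.05, so its scale is log2 signal with no background subtraction, centring or scaling between arrays. Its column medians were 7.1, 6.88, 6.99 and 7.15 for EV replicates 1 to 4 and 7.25, 7.32, 7.54 and 7.43 for CYP replicates 1 to 4. The series' design text describes filtering, a floor of 1, log2 transformation, 75th percentile normalisation and a moderated test in Genespring. That text names a contrast of another tissue and line for the test, so the contrast used here, CYP against EV, was taken from the sample labels.

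The values analysed here were computed from the processed intensity. Of the array's spots, 1319 control spots were left out and 61657 spots of 57157 probes were used. Each array was scaled to a common 75th percentile, a floor of 1 was applied and log2 was taken. A spot flagged as a non-uniformity or population outlier was treated as missing (136 to 208 spots per array), and the 10 spots of each of 500 repeated probes were averaged, such a probe counting as well above background where most or an equal share of its spots were. Probes were kept where they were well above background on all 4 arrays of at least 1 group, which left 34631 probes. No spot was saturated. CYP was compared with EV over all 8 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, without covariates, as a two-sided moderated test with Benjamini-Hochberg adjustment. A probe is called higher or lower where its adjusted p is under 0.05. Where several probes name 1 gene model, the model is represented by the probe with the highest mean log2 signal. A probe below background on every array of a group has no measured level there, so a limit fold is given. For it, the bright group's mean log2 value was set against a mean over the dim group's arrays. Each dim array entered with the higher of the probe's own value and the lowest value of any probe well above background on that array. The limit fold is not a strict lower bound, since a probe above that lowest value can still fail detection. On EV replicate 1 the gene model NIATv7_g40579 stood at 4.092 without being well above background, where the lowest such value was 3.98.

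The array names probes by gene model or probe numbers without symbols or descriptions. Of the probes, 48408 name a NIATv7 model, 3656 a NIATv1 model and 2283 an XLOC model, in all 37333 models, and 2810 carry a PRID number and no model. None of these names (0) matched an entry of the RefSeq table of 39977 genes of assembly NIATTr2 supplied for names, which holds no probe sequences. The 40 gene lists fixed in advance, and the silenced genes themselves, could therefore not be located among the probes, 0 lists had a matching name, and the planned tests of lists and target genes are not reported here. The rule for named genes required an informative annotation, so no gene qualified; in its place the text names the 2 gene models with the largest rise and the 2 with the largest fall among those called, with all 4 CYP values on one side of all 4 EV values. They stand under the identifiers of the files. The genome build and coordinates were not used here.

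The slide and the scan of each array were read from the file headers. The 8 arrays lay on 2 slides, each scanned once, and each slide held 2 EV and 2 CYP arrays, so that slide and group could be separated. The labels do not say whether replicate samples came from separate plants; p-values measure the spread between these samples. The number of arrays limits the precision.

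The procedure was tested on simulated data built from the real means and standard deviations of 34623 probes. Of 50 probes changed by each size of fold, 1 was recovered with the right sign at 1.5-fold, 21 at 2-fold, 40 at 4-fold and 41 at 8-fold, and 3 of 106 calls were false. Few probes were changed in that run, which makes the adjustment stricter than in the data, where 43.8% were called. Its recovery figures therefore do not describe the real comparison. When the called changes themselves were planted, 13687 probes were called, 2.93% of them falsely and 0 with the wrong sign. All other probes then had no change and independent noise, so a low false share was set by construction and is not an estimate for the data.

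Alternatives fixed before the data were examined were normexp background correction (with an offset of 50, on the median signal in place of the planned spot mean), quantile and median normalisation, the floor set before scaling, other filters on dim probes, outlier spots kept, slide or replicate number as a block, each slide alone, each array left out in turn, the deposited value table, a variance trend with robust fitting, array weights and stricter thresholds. Cyclic loess, scaling on the E1A spike-in control probes and a median change set to 0 were added after the data were seen. Figures were drawn with matplotlib 3.10.9.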

Results

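Transcript abundance was profiled in leaves of Nicotiana attenuata after virus-induced gene silencing, a method in which a modified plant virus carrying a fragment of a plant gene triggers the breakdown of that gene's transcripts. Silencing was directed at NaCYP736A, of the cytochrome P450 family, and plants infected with an empty vector (EV) served as controls. According to the series title, the study concerns hydroxylation of diterpenoids, defence compounds of this plant, and the toxicity of such compounds to the plant itself. All leaves received methyl jasmonate, an elicitor of defence responses, at 150 µg per leaf and were harvested 3 days later. The comparison asked which transcripts differed between CYP-silenced and EV leaves under this elicitation, with 4 arrays per group. Silencing of the geranyllinalool synthase gene, which the design text also describes, was not analysed here.

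The arrays carried 57157 probes for plant transcripts. On the EV arrays 33945 to 34891 probes were well above background, and on the CYP arrays 35315 to 36107. The median probe reached 3.89 to 5.1 times its local background on EV arrays and 4.91 to 6.17 times on CYP arrays. The number of detected probes was 34517 ± 431 (SD, n = 4) in EV and 35639 ± 352 (SD, n = 4) in CYP, and the 2 groups did not overlap (exact permutation test, two-sided p = 0.0286, the smallest that 4 against 4 arrays can give). The CYP arrays were also brighter before scaling, with a 75th percentile of 1520 ± 194 intensity units against 1067 ± 138 in EV (SD, n = 4), a ratio of 1.42 (exact permutation test, two-sided p = 0.0286). The files name probes by gene model number and do not pair these numbers with gene names. NaCYP736A transcripts could therefore not be located, and the degree of silencing could not be checked against the labels.

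CYP-silenced leaves differed from EV leaves across much of the measured transcriptome. Of 34631 probes kept, 6197 were higher and 8986 were lower in CYP, together 43.8% of the probes (limma, Benjamini-Hochberg adjusted p under 0.05). Among the called probes, 3454 rose by 2-fold or more and 4353 fell by 2-fold or more. Computed folds of 16 or more were reached by 694 rises and 152 falls, but many of these rest on values near or below background in 1 group. Among the 31566 probes well above background on all 8 arrays, 226 rose and 68 fell by 16-fold or more. The median called rise was 1.14 on the log2 scale (quartiles 0.68 and 2.32) and the median called fall was -0.97 (quartiles -1.54 and -0.66). Limma's estimate of the share of unchanged probes was 37%. For 14868 probes (42.9%) all 4 CYP values lay on one side of all 4 EV values, against 2.86% by chance.

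These directions are relative to a scaling at each array's 75th percentile, under which the median change of all kept probes was -0.11 on the log2 scale. The share of rises among the calls was 40.8% under this scaling, 53.2% after cyclic loess normalisation, 51.9% with the median change set to 0 and 61.7% (4168 higher and 2591 lower) when 7 arrays were scaled on spike-in control probes, with EV replicate 1 left out; the last 3 scalings were chosen after the data were seen. Under the normalisations fixed in advance falls stayed the more numerous. Rises made up 44.2% of the calls after quantile normalisation, 43.1% after median normalisation and 35% with normexp correction. Cyclic loess and the median change set to 0 brought the median change to 0.02 and 0, which by itself draws the shares towards even. Whether rises or falls were the more numerous therefore depended on the scaling. Without the filter on dim probes the median change was -0.35, but the added probes were not well above background throughout either group. After scaling, the lowest signal well above background was 3.54 to 3.9 on CYP arrays and 3.98 to 4.47 on EV arrays. The detection limit itself thus lay lower in CYP, and falls among the added probes cannot be told from this shift.

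The arrays separated by group. The first principal component held 73.7% of the variance and placed the EV arrays between -145.8 and -99 and the CYP arrays between 92.8 and 154.5. The second component, with 10.3%, spread the arrays within both groups, from -57.3 (CYP replicate 4) to 92.7 (CYP replicate 2) in CYP and from -30.5 (EV replicate 2) to 50.5 (EV replicate 1) in EV. Pearson correlations across probes, which are not independent replicates, averaged 0.981 (range 0.971 to 0.988) among EV arrays and 0.964 (0.949 to 0.976) among CYP arrays. Between EV and CYP arrays they averaged 0.871 (0.823 to 0.912). The mean correlation within groups exceeded that between groups by 0.101, and no other of the 35 splits of the arrays into 4 and 4 gave more than 0.025 (exact permutation test, one-sided p = 0.029).

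**Figure D1:**
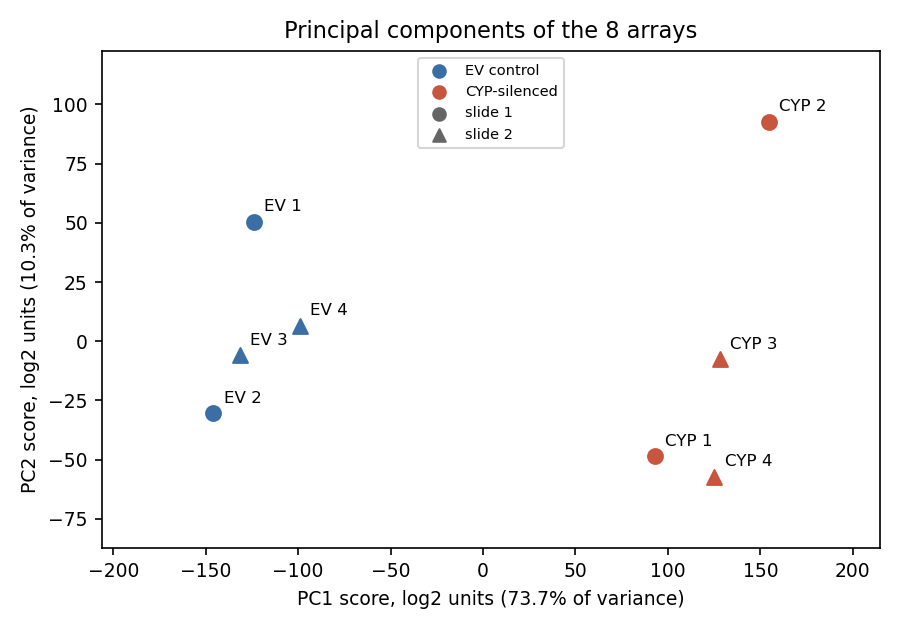
Scores of the 8 arrays on the first (x axis, 73.7% of variance) and second (y axis, 10.3%) principal components of the normalised log2 signals; each point is 1 array, coloured by group and shaped by slide. The EV arrays lie between -145.8 and -99 on the first component and the CYP arrays between 92.8 and 154.5, on both slides.

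Both slides showed the difference. Each slide held 2 arrays of each group, so the slides gave 2 separate measurements of every change. With the slide as a block in the model, 6451 probes were higher and 9211 lower. On slide 1 alone 1314 probes were higher and 617 lower, and on slide 2 alone 4335 were higher and 6235 lower (limma, adjusted p under 0.05). Of all kept probes 85.7% had the same sign of change on both slides, and of the 1931 called on slide 1, 1927 (99.8%) had the same sign on slide 2. The changes on the 2 slides correlated at r = 0.92 across probes.

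Under the 75th percentile scaling the brightest transcripts leaned towards lower signal in CYP. Falls also outnumbered rises among them with normexp correction, spike-in scaling and the median change set to 0, but not after quantile or cyclic loess normalisation. Among 3854 probes with a mean log2 signal over 13, 530 (13.8%) rose and 1338 (34.7%) fell, with a median change of -0.28. In the 4 classes between 5 and 13, 17.7% to 18.1% of probes rose and 24.4% to 24.8% fell. Among the 1678 dimmest probes, under 5, 479 rose and 479 fell, together 57.1% of the class. So dim a probe can pass the filter through the group where it is higher, which can raise the share called in this class. In the brightest class rises made up 28.4% of the calls, against 42.6% among all other probes. These shares were 31.8% and 35.5% with normexp background correction, 40.2% and 63.9% with spike-in scaling and 40% and 53.5% with the median change set to 0. They were 50.2% and 43.4% after quantile normalisation, which turned the order, and 53.3% and 53.1% after cyclic loess. Both of these methods remove shifts shared by probes of like signal, so the loss of the lean under them does not decide whether it was real.

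**Figure D2:**
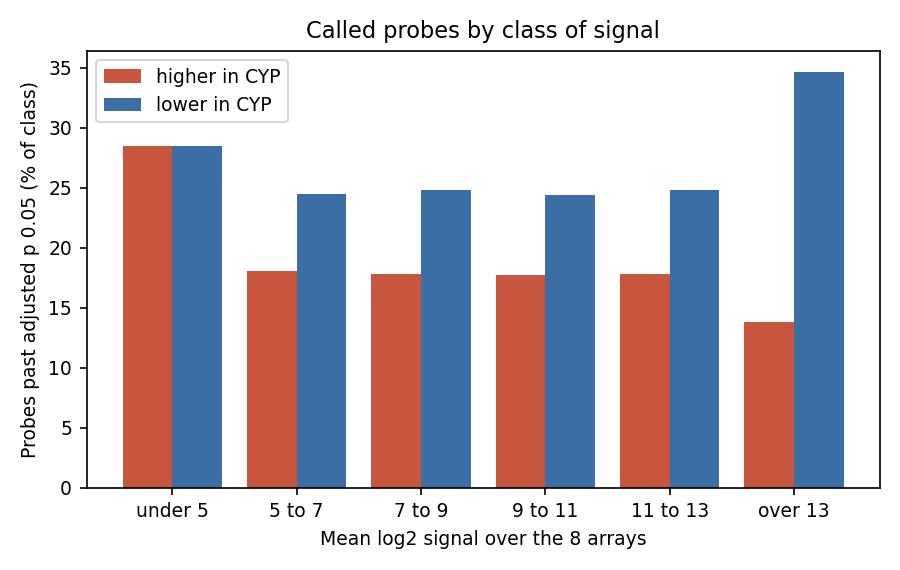
Share of probes called higher (red) or lower (blue) in CYP (y axis, percent of the probes in the class, limma adjusted p under 0.05) in 6 classes of mean log2 signal over the 8 arrays (x axis). Falls reach 34.7% and rises 13.8% in the brightest class under the 75th percentile scaling. An excess of falls in that class was also seen with normexp correction, spike-in scaling and the median change set to 0. It was not kept after quantile or cyclic loess normalisation, which remove shifts shared by probes of like signal. In the dimmest class a probe can pass the filter through the group where it is higher, which can raise the share called.

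Some probes were well above background in one group alone. Detection was called on each array before scaling, and the CYP arrays were the brighter ones, with a 75th percentile 1.42 times that of EV and more probes detected in all, which moves with the counts given here. There were 577 probes well above background on all 4 CYP arrays and on no EV array, and 125 probes with the opposite pattern. Of the former 554 and of the latter 125 were called by limma. Both sets were picked for a difference in detection on the same arrays, so these calls are no separate support. For 12 of the 577 probes the limit fold did not exceed 1 and no fold is given. Among the others its median was 4.03, higher in CYP, and it was 4 or more for 284 probes and 64 or more for 18. The largest limit fold was 704. For the 125 probes the median limit fold was 3.2, lower in CYP, with 42 probes at 4 or more and 0 at 64 or more. Without CYP replicate 1 the 125 became 213, so that array set much of this smaller count.

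Among gene models, each represented by its brightest probe and without overlap of the 2 groups, the largest computed rises were those of NIATv7_g40579 and NIATv7_g37556. NIATv7_g40579 had a log2 signal of 3.28 ± 1.18 in EV and 14.18 ± 1.48 in CYP (SD, n = 4), a change of 10.91 ± 0.81 (SE; limma, adjusted p = 7.1e-05). NIATv7_g37556 stood at 3.36 ± 1.9 in EV and 14.06 ± 0.88 in CYP (SD, n = 4), a rise past the threshold (limma, adjusted p = 0.00011). Each of these models was well above background on all 4 CYP arrays but on only 1 of the 4 EV arrays, EV replicate 4, so the EV level, the size of the change and the rank of these models among the largest rises are not fixed by the data. On slide 1 neither was above background on an EV array. The limit folds there were 1970 for NIATv7_g40579 and 1330 for NIATv7_g37556, higher in CYP. On slide 2, with 1 of 2 EV arrays above background, the computed changes were 9.83 and 9.17. With normexp correction, which adds an offset of 50 to every signal, they were 7.78 and 7.29.

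Under the same rule the largest falls were those of NIATv7_g25488 and NIATv7_g18368. A probe of another NIATv7 model had a change of -8.58, but the brighter probe that represents that model had -7.51. NIATv7_g25488 went from 14.77 ± 0.18 in EV to 6.04 ± 1.09 in CYP (SD, n = 4) and was above background on all 8 arrays. Its change was -8.73 ± 0.48 (SE; limma, adjusted p = 2.7e-05), with a 95% interval of -9.83 to -7.63. NIATv7_g18368 went from 13.67 ± 0.74 to 5.98 ± 3.3 (SD, n = 4), with 3 of the 4 CYP arrays above background. Its change was -7.68 ± 1.45 (SE; limma, adjusted p = 0.0039), with a 95% interval of -11.01 to -4.36. Its size and its rank rest on CYP replicate 2, the array not above background, without which the change was -6.26. On slides 1 and 2 alone NIATv7_g25488 changed by -9.09 and -8.38. For NIATv7_g18368 the values were -9.17 and -6.2, and the limma adjusted p on slide 1 alone was 0.11, the highest over 24 alternatives (range 0.00036 to 0.11). Which genes these 4 models are is not given in the sources used here.

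**Figure D3:**
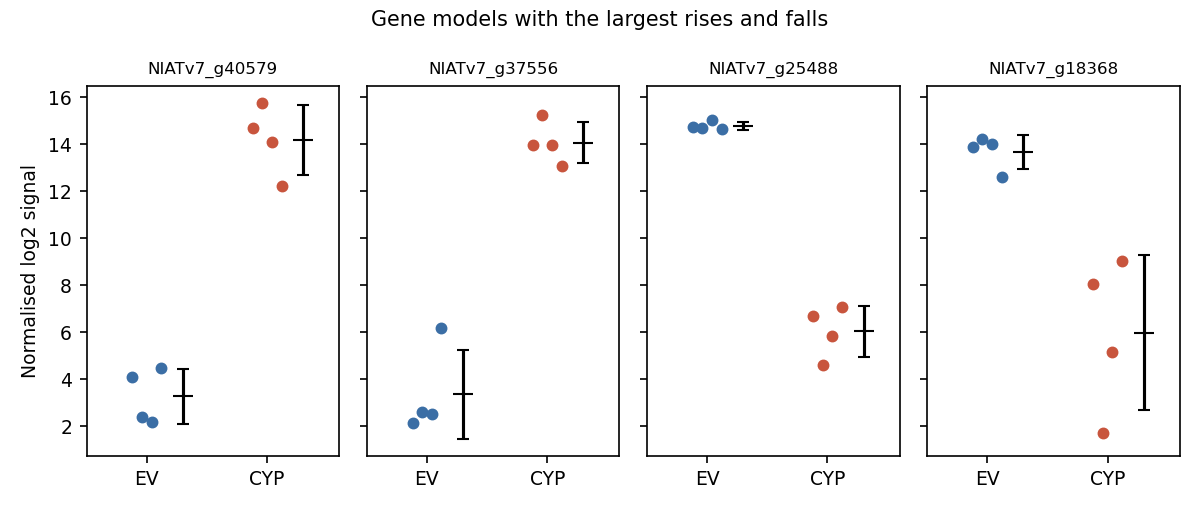
Normalised log2 signal (y axis) of the 4 named gene models on the 4 EV and 4 CYP arrays (x axis); points are arrays, and the bar beside them is the mean with its SD. All 4 CYP values lie on one side of all 4 EV values in each model, and the EV values of NIATv7_g25488 have an SD of 0.18.

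Counted by gene model, 4134 of 22243 models were higher and 5656 lower in CYP, together 44% of the models. By the kind of probe name, 43.7% of NIATv7 probes, 42.3% of NIATv1 probes and 40.7% of XLOC probes were called, and 47.7% of the PRID probes, which name no model; differences between these shares were not tested. In the NIATv1 probes 108 rose and 100 fell, and in the XLOC probes 151 rose and 253 fell. Of 2390 models with at least 2 called probes, 2334 (97.7%) had all their called probes moving one way, against 51.2% for independent pairs of probes. In 56 models probes were called in both directions.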

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

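The comparison of control probes was chosen after their values had been seen. NIATv7_g37556 stood apart in 1 EV array. Its log2 signal was 6.19 in EV replicate 4 and between 2.15 and 2.58 in the other 3 EV arrays, where it was not above background. The gap to these background values took up 0.893 of the range of the EV values, above Dixon's 95% critical value for 4 samples. This was the only one of 18 groups of 4 values checked that passed, and chance passes about 1 in 20. Without EV replicate 4 no EV array was above background, and the limit fold was 895, higher in CYP. Of 22 families of control probes other than E1A and the corner probes, 0 were both above background and higher on every CYP array than on every EV array.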

How the results depend on the processing

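Cyclic loess, spike-in scaling, the median change set to 0 and gene models as probe means, and the alternatives for probes detected in 1 group, were chosen after the data were seen. No named gene model turned direction, which their choice by large called changes without overlap made near certain. Over 22 alternatives with 1 EV array above background NIATv7_g40579 ranged from 7.78 to 11.56 and NIATv7_g37556 from 7.29 to 11.03. With 0 such arrays, on slide 1 alone and without EV replicate 4, the limit folds of NIATv7_g40579 were 1970 and 951. Those of NIATv7_g37556 were 1330 and 895, all higher in CYP. NIATv7_g25488 ranged from -9.09 to -7.89, and these 3 kept their call throughout. NIATv7_g18368 ranged from -9.17 to -6.16 and lost its call on slide 1 alone (-9.17, limma adjusted p = 0.11, range 0.00036 to 0.11). The correlation within groups exceeded that between groups by 0.032 without a filter and 0.102 after quantile normalisation. On deviations from slide means, another measure, the excess was 1.48. Each was the highest of all splits. Of these and the counts of calls under all alternatives, 146 stayed within 1.5 times the main count or past the threshold and 19 did not. With no filter on dim probes 19063 probes and 12573 gene models were lower (median change -0.35), but the added probes failed the detection rule. On slide 1 alone 1314 probes were higher and 617 lower, all of them by 2-fold or more, and 1012 gene models were higher and 408 lower. Slide 2, with as many arrays per group, gave 4335 probes higher and 6235 lower, so fewer arrays alone do not explain the low counts. At an adjusted p under 0.01 there were 3667 probes higher and 5041 lower, and 2550 gene models higher and 3226 lower; requiring 2-fold left 3454 and 4353 probes and 2502 and 2805 gene models. With spike-in scaling, under which the median change was 0.19, 2591 probes and 1709 gene models were lower, 2530 of these probes by 2-fold or more. The share of rises among the calls was 40.8% in the main setting, 25.4% without the filter and 68% on slide 1 alone. Leaving out 1 array at a time gave 4809 to 6316 probes higher and 6820 to 9101 lower, 3227 to 3631 and 3816 to 4999 by 2-fold or more, and 3229 to 4231 gene models higher and 4363 to 5748 lower; the lowest counts came without EV replicate 3. Probes on CYP arrays alone then numbered 613 to 749 and on EV arrays alone 140 to 213, and with only 2 arrays per group they numbered 1102 and 319 on slide 1 and 1176 and 364 on slide 2. With the replicate number as a block, 5115 probes were higher and 6987 lower; deviations of same-numbered arrays from their group means correlated at -0.28, -0.27, 0.22 and 0.24, and 4 of 8 arrays correlated best with their own number. Scan and slide coincided, so scan was not blocked. Alternatives for target genes and gene lists were not run, as probes could not be named. Probes near background limit the largest folds: the lowest log2 signal well above background was 3.54 to 4.47.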

Other observations

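The tests of chance in the spread within groups, of dim probes, of the order of gene model numbers, of paired probes, of coding pieces and of the spike-in controls, and cyclic loess as a setting, were chosen after the result or a closely related value had been seen.

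Some gene models had several probes, which allowed a comparison within models. Probe sequences were not compared, so paired probes are not known to bind different stretches of a transcript. A high correlation of a pair is therefore not shown to come from separate measurements. Among 4376 gene models with probes for 2 transcript models, all above background on all 8 arrays, the changes of the pair correlated at 0.963 and differed in 100 models (2.29%; limma on the difference of the pair, adjusted p under 0.05), in 29 of them by 2-fold or more. Among 2137 models with 2 probes in numbered coding pieces of 1 transcript model, the changes correlated at 0.768 and differed in 287 models (13.4%), in 98 by 2-fold or more. In 20 of these and in 8 of the former the called changes had opposite signs. The higher-numbered piece was not systematically changed against the lower-numbered: the median difference was -0.094 ± 0.015 in EV and -0.102 ± 0.031 in CYP (SD, n = 4; exact permutation test, two-sided p = 0.8).

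The bright E1A spike-in control probes, which report control RNA added to each sample before labelling, averaged 9.06 on the log2 scale on EV replicate 1, against 10.77 to 11.48 on the other EV arrays and 11.12 to 11.55 on the CYP arrays, while the 75th percentile of the plant probes on that array, 10.23, was the highest of the EV arrays (9.84 to 10.23).

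The called probes, 15183 in all, made up 43.8% of those kept. Chance among the arrays can be excluded only as far as 35 splits allow: 1 of them, the real one, gave as many, and the highest other, which followed the slides, gave 71, though every other split mixes EV and CYP arrays, which by itself lowers its count. Higher brightness of the CYP arrays would bend the signal scale and so shift probes by their brightness alone, yet 14983 probes were called after cyclic loess removed such trends. Fewer were called with spike-in scaling, 4168 higher and 2591 lower without EV replicate 1, against 5369 and 7813 without that array under the main scaling. Cyclic loess does not address effects of labelling or RNA amount on single probes, which were not tested. A contribution of 1 slide is argued against by the correlation of 0.92 between the changes on slides 1 and 2. A response to silencing stays as a hypothesis, found and tested on the same arrays.

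CYP arrays varied more among themselves than EV arrays: the median SD over probes was 0.302 in CYP and 0.216 in EV, a ratio of 1.4. The ratio was 1.17 with CYP replicate 2 left out, and 1.36 to 1.39 with any other CYP array left out, so that array accounts for part of the pattern but not all. Dim probes alone do not account for it, since the ratio was at least 1.19 in each of 6 classes of signal and reached 1.51 among the brightest. Chance among 8 arrays stays possible: the median deviations from the group mean were 0.172, 0.186, 0.114 and 0.117 in EV and 0.181, 0.254, 0.185 and 0.196 in CYP (exact permutation test, two-sided p = 0.0857), and EV replicates 3 and 4, the lowest, shared slide 2. Uneven silencing between plants may also contribute, but was not tested because NaCYP736A transcripts could not be located.

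Gene models with adjacent NIATv7 numbers tended to change alike. Over 10174 adjacent pairs Spearman's rho of the changes was 0.082, above the highest of 1000 shuffled orders (0.033), and it fell to 0.022 at a step of 2 and to -0.013 at a step of 3. Of 2065 adjacent pairs with both models called, 1221 (59.1%) changed one way, against 51.2% expected from the shares of rises and falls and at most 1108 pairs in shuffled orders. Spots side by side on the array are not the source, since spots in adjacent columns had a rho of -0.003. If the numbers follow the order of genes in the assembly, neighbouring copies of one gene family, or probes that bind transcripts of both, may be behind it; neither was tested here, as probe sequences and positions were not used.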
